A study of Mus musculus with 48 samples.

How the data were processed

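The series holds 48 arrays of total RNA from mouse hypothalamus and preoptic area, taken at 12 ages from embryonic day 10 (E10) to postnatal day 42 (P42), with 1 array for each combination of age, strain and sex. The strains were the inbred C57Bl/6 and the outbred stock CD-1. Per the labels' protocols, tissue was dissected into an RNA preservative, and RNA was purified on spin columns and amplified in 1 round with an oligo-dT primer. The deposited values are array intensities summarised as MAS5-type signal on a linear scale, 1 value per probe set and array. The submitters' processing notes name GCOS 1.4 and MAS5. No further step is given in the sources used here. In the deposited table the mean signal between the 2 and 98 percentiles was 150.0 in every array, with a largest deviation of 0.007%, so no further scaling was applied. The labels give 1 array per combination and do not say how many animals stand behind an array. The p-values therefore measure how single arrays scatter around an additive effect of age, strain and sex, a spread that may be partly technical. The number of arrays sets the precision of every value, and no counting depth applies.

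Signal was transformed as log2(signal + 16), where 16 is the power of 2 nearest to the 20th percentile of all deposited values (15.03). Fold changes are on this scale and understate the change of dim genes. Of 45101 probe sets, 64 are controls, 34945 carry 1 gene symbol in the platform annotation, 932 carry several and 9160 are unlisted there and stay unnamed. Symbols were updated through a RefSeq gene table (GRCm38.p6), and no coordinates were taken from it. A probe set was tested when it lay above the median of its array in at least 4 of the 48 arrays, and each gene was represented by its probe set with the highest mean log2 value. This left 13689 genes. Other probe sets of a gene were tested in a separate fit of 30080 probe sets, and disagreements are given beside the gene.

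Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) in a single fit of all 48 arrays with age, strain and sex as terms (34 residual and 7.45 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p-values of genes are from limma throughout. They are from this fit unless an interaction, a sex difference at P21 and P42 or another fit is named. All tests are two-sided. The comparisons were an F test over the 12 ages, E14 against E10, E18 against E14, P21 against P0, P42 against P21, each age against the age before it, CD-1 against C57Bl/6, males against females at all ages and at P21 and P42, and the interactions of sex and of strain with stage (E10 to P0 against P21 and P42) and of strain with sex. The comparisons, their models and the alternatives to them were fixed before the data were examined, as were 29 gene lists for cell types, pathways, neighbouring brain regions and sex-linked or strain-variable genes. Of 405 list members, 371 had a usable probe set and 348 were tested, and the others were not analysed here. Lists were compared with the other genes by limma's camera with its preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated for each list. Members of a list were also counted after adjustment over the list alone. Genes were named by rule: the 8 largest rises and falls of a comparison with the same sign in all 4 series of strain and sex (for strain and sex, in at least 20 of the 24 matched pairs of arrays), the 3 largest called changes of each list, and a set of key hypothalamic genes.

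For the stage of an embryo, each of the 32 arrays of E11 to E18 was placed at the nearest point on the age axis of the other strain, or of the other sex, and the difference was tested over the 8 ages by an exact sign-flip test of 256 flips. Fits of 3 comparisons were tested on simulated data with known changes in about 200 of the 13689 genes, in 3 rounds. A list test and the age placement were simulated apart, and the other comparisons were not simulated. For E14 against E10, 29.4% of changes of 1.5-fold, 68.7% of 2-fold and 99.5% of 4-fold changes were recovered, and 4.6% of calls were wrong. Between the strains 96.5%, 100% and 100% were recovered, with 5.72% of calls wrong, and for the interaction of strain with stage 23.9%, 64.2% and 98.5%, with 5.82% wrong. Without an added change 0 of 10 simulations called the neuropeptide list, and with log2 changes of 0.5 or 1 10 of 10 did, with 0 of 270 other lists called. The noise of each gene was drawn independently, so these simulations do not cover lists whose members vary together. In the data the estimated correlation of the neuropeptide list was 0.335. Added shifts of 0.5 and 0.25 days between the strains were recovered as 0.49 and 0.386 days (exact p = 0.00781 each), and no shift as 0.042 days (exact p = 0.273). Between the sexes they were recovered as 0.494 and 0.389 days (exact p = 0.00781 each), and no shift as 0.061 days (exact p = 0.266).

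The alternatives were offsets of 4 and 64, no filter and a stricter one, quantile normalization, median centring, every probe set on its own, probe sets that can match several transcripts used last, eBayes without trend and with robust estimates, array weights, the 4 series of strain and sex as a block, fits on the ages compared, on 1 sex, 1 strain or 1 stage, and leaving out arrays, ages and series in turn. Chosen only after the data were seen were fits without the array labelled C57Bl/6 P42 male (for strain also at P21 and P42 alone), without it and the array labelled C57Bl/6 E16 male, without the array labelled C57Bl/6 E14 female, with CD-1 arrays alone, with arrays matched by age and strain (for sex) or by age and sex (for strain) as a block, and with the beta-actin 3' to 5' ratio of each array as a covariate. The fits with the covariate and those with matched arrays as a block kept the array labelled C57Bl/6 P42 male. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.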

Results

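Transcript levels in mouse hypothalamus and preoptic area were followed across the embryonic days E10 to E18, the day of birth (P0), P21 and P42, and compared between strains, sexes and ages. Each age had 4 arrays, a female and a male of C57Bl/6 and a female and a male of CD-1, and the tests covered 13689 genes. Levels below are MAS5 signal as mean ± SD of the 4 arrays of an age (n = 4), and log2 changes carry the SE of the limma fit. The median signal of an array lay between 50.6 and 90.5 in C57Bl/6 and between 47.0 and 67.0 in CD-1, and no pair of the 48 arrays shared more than 2 identical values of 45101.

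The label of an adult array stood against its markers of stage. In the array labelled C57Bl/6 P42 male, the myelin gene Mobp gave a signal of 61.6 against 932 to 1250 in the other 3 P42 arrays, while Sox11 (5210) and Dcx (4690), genes of newborn neurons, stood at embryonic levels. This array correlated best with the C57Bl/6 E16 male (0.982 over genes) and at most at 0.852 with a P42 array. It also carried both the female transcript Xist (1230) and the Y-linked Eif2s3y (120), as did the array labelled C57Bl/6 E16 male (1850 and 60.4). Both arrays were kept where the design put them, and counts are also given without the array labelled C57Bl/6 P42 male. The array labelled C57Bl/6 E14 female carried collagen transcripts far above the other E14 arrays (Col3a1 3500 against 120 ± 71.2, n = 3). Beta-actin 3' to 5' ratios, which rise as RNA breaks down, were 4.22, 3.77 and 4.49 in the C57Bl/6 P21 female, P21 male and P42 female, against a median of 1.1 (1.03 to 1.21) in CD-1 arrays and 1.38 in C57Bl/6 arrays.

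Age dominated the variation between arrays. Of 13689 genes, 11008 (80.4%) differed across the 12 ages by the limma F test (11171 without the array labelled C57Bl/6 P42 male). The highest mean log2 level fell at E10 for 3129 (28.4%) of these genes, at E11 for 1321 (12%) and at P21 for 2724 (24.7%), against 221 at E14. Without the array labelled C57Bl/6 P42 male, 1594 were highest at P21 and 1621 at P42. The highest mean fell at E10 for 14 of 19 cell cycle genes, at E12 for 9 of 15 genes of progenitors and radial glia, and at E13 or E14 for 22 of 37 hypothalamic patterning factors (11 at each age), while proneural genes were spread from E10 to E18 (5 of 17 at E12). Without the array labelled C57Bl/6 P42 male it fell at P42 for 21 of 24 neuropeptide and transmitter genes, and at P21 for 16 of 25 synaptic genes, 8 of 14 astrocyte genes, 8 of 11 myelin genes and 9 of 15 clock genes. With that array in the P42 means, 16, 23, 12, 11 and 12 genes of these 5 lists were highest at P21. The first principal component held 48.6% of the variance and the second 17.1%.

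**Figure D1:**
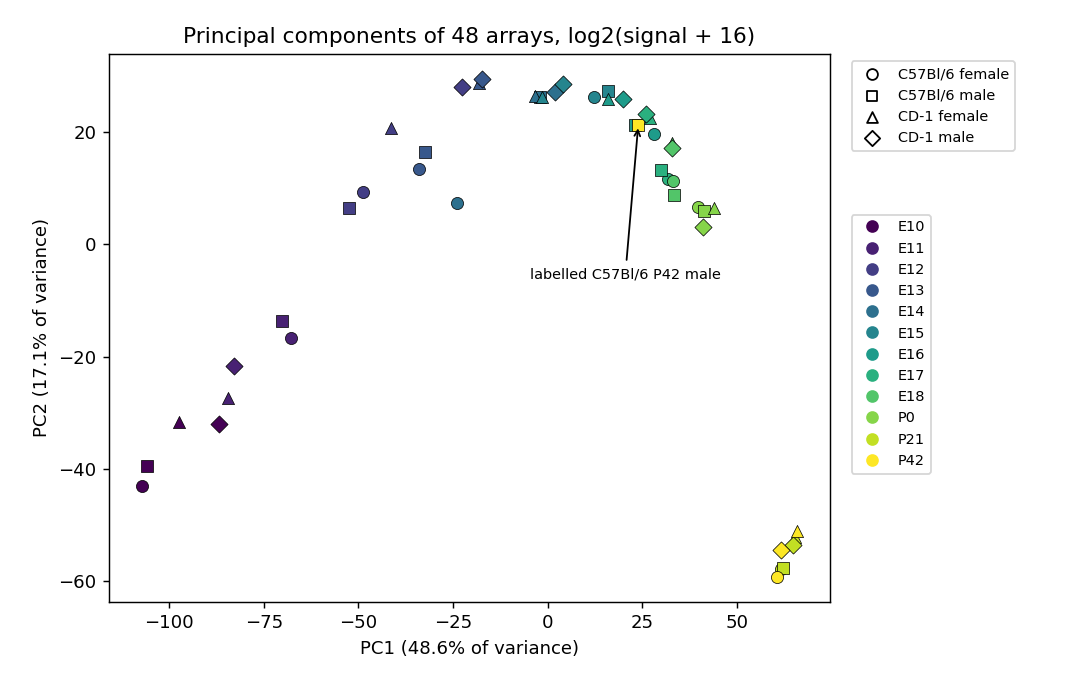
Scores of the 48 arrays on the principal components PC1 (x axis, 48.6% of variance) and PC2 (y axis, 17.1%) of log2(signal + 16), coloured by age, with a symbol for each strain and sex. Arrays run from E10 at the lower left to P21 and P42 at the lower right, and the array labelled C57Bl/6 P42 male lies among late embryonic arrays at a PC1 score of 23.9.

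Between E10 and E14 neuronal genes rose and cell cycle genes fell. Tmem130, a membrane protein gene, rose from 20.1 ± 5.53 to 1970 ± 336, 54.9-fold, and Mapt, which encodes the microtubule protein tau of axons, from 145 ± 147 to 4960 ± 1030 (log2 change 5.65 ± 0.36). Stmn4, the adhesion gene Chl1, Gpm6a, the RNA-binding protein gene Celf5 and Resp18 rose 30.1- to 32.5-fold. Embryonic beta-globin Hbb-bh1 fell from 8460 ± 1540 to 64.8 ± 33.3 (-6.77 ± 0.51). Lin28a and Sall4, genes of early undifferentiated cells, fell by 4.26 and 4.12 on the log2 scale, and the retinoic acid binding protein genes Crabp1 and Crabp2 31.9- and 25.1-fold. Pole, the catalytic subunit of a replicative DNA polymerase, fell by 3.96. Adjusted p-values of these genes ran from 9.8e-24 for Gpm6a to 1.67e-11 for Crabp1, and each gene moved the same way in all 4 series of strain and sex. In all, 7353 genes were called, 3831 higher and 3522 lower at E14, of which 3253 changed at least 2-fold (1881 up, 1372 down).

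Of the factors that pattern the hypothalamus, 24 of 38 tested members were higher at E14 and 3 lower (25 and 3 adjusted over the list alone). Their median change was 1.27 (camera adjusted p = 0.000192, adjusted p = 0.531 with an estimated correlation). Otp, needed for neuroendocrine neurons of the paraventricular region, rose from 193 ± 162 to 2330 ± 298 (3.77 ± 0.29). Lhx1 rose by 3.47, Sim1 by 3.16, Dlx1 of GABAergic progenitors by 2.47 and Nkx2-1 of the ventral hypothalamus by 1.27. Rax (-0.33, adjusted p = 0.461), Six6 (0.19, adjusted p = 0.64), Lhx6 (0.61, adjusted p = 0.203) and Foxb1 (0.58, adjusted p = 0.09) were not called. Of 17 proneural and newborn neuron genes 13 rose and 2 fell (median 1.97, camera adjusted p = 0.000655, adjusted p = 0.543 with an estimated correlation). Dcx was at 3.62, Stmn2 at 3.42 and Neurog2 at 2.60. Of 25 synaptic genes 20 rose and 0 fell (camera adjusted p = 2.12e-09, adjusted p = 0.422 with an estimated correlation). Gad1, the GABA-synthesising enzyme, rose 22.1-fold, the glutamate transporter gene Slc17a6 16.0-fold and Syt1 12.5-fold. The neuropeptide and transmitter list had 12 of 24 members higher and 0 lower (median 0.90, camera adjusted p = 0.012, adjusted p = 0.763 with an estimated correlation). Pmch, which encodes melanin-concentrating hormone, rose from 40.8 ± 7.09 to 450 ± 73.5, and Tac1 by 2.94, Trh by 2.21, Npy by 1.49 and Pomc by 1.35. Avp (0.92, adjusted p = 0.0617), Oxt (0.05, adjusted p = 0.931) and Hcrt (-0.14, adjusted p = 0.777) were not called. Adjusted over the list alone the counts of these 3 lists were the same.

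Cell cycle genes fell at E14, with 18 of 19 lower and 0 higher (median -2.36, camera adjusted p = 1.69e-10, adjusted p = 0.422 with an estimated correlation). Among them were the mitotic kinase gene Bub1 at -3.19 and the replication licensing gene Mcm5 at -3.04. Genes of mesenchyme and meninges fell in 8 of 10 cases (camera adjusted p = 0.00739, adjusted p = 0.745 with an estimated correlation), with Twist1 at -3.74 and Igf2 at -2.46. The array labelled C57Bl/6 E14 female stood above the other E14 arrays for this list. Progenitor genes split, with 6 of 16 higher and 4 lower (camera adjusted p = 0.775): Fabp7 of radial glia rose by 2.51 while Hmga2 and Id3 fell by 3.34 and 2.73. Patterning signals had 2 of 18 higher and 8 lower (camera adjusted p = 0.0768). Bmp4 and Gli1 were lower, and Shh was at -0.12 (adjusted p = 0.727). Astrocyte genes had 5 of 14 higher and 1 lower, the glutamate transporter gene Slc1a2 at 2.94 and Gja1 at -2.13. Oligodendrocyte precursor genes had 2 of 7 higher and 2 lower, Olig1 at 3.11 and Pdgfra at -2.37. Microglial genes had 6 of 12 higher and 1 lower, Ctss at 2.14. Blood vessel genes had 2 of 12 higher and 5 lower, the pericyte gene Rgs5 at 3.06 and the endothelial receptor gene Kdr at -1.16. Imprinted genes had 6 of 13 higher and 3 lower, with the Prader-Willi region genes Ndn and Magel2 up by 2.87 and 2.81. Hormone receptors had 6 of 18 higher and 1 lower, the thyroid hormone receptor gene Thra at 2.92. Markers of cerebral cortex had 5 of 6 higher, Neurod6 at 3.10. Members called higher and lower were 4 and 2 of 16 for the circadian clock, 3 and 1 of 10 for immediate early genes, 2 and 0 of 11 for cholesterol synthesis, and 1 and 0 of 11 for myelin. They were 0 and 2 of 5 for red blood cells, 0 and 2 of 5 for choroid plexus, 3 and 0 of 5 for ependymal cells, 1 and 1 of 5 for pituitary, 1 and 0 of 4 for striatum and 3 and 1 of 6 for thalamus. None of the lists after the mesenchyme genes passed the camera test (adjusted p between 0.0768 and 0.988). Adjusted over the list alone the counts of this paragraph differed for progenitors (6 and 5), hormone receptors (5 and 1), microglia (7 and 1) and choroid plexus (0 and 1). The fit of all arrays gave 6246 to 7764 calls when the arrays compared or the series were left out in turn.

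**Figure D2:**
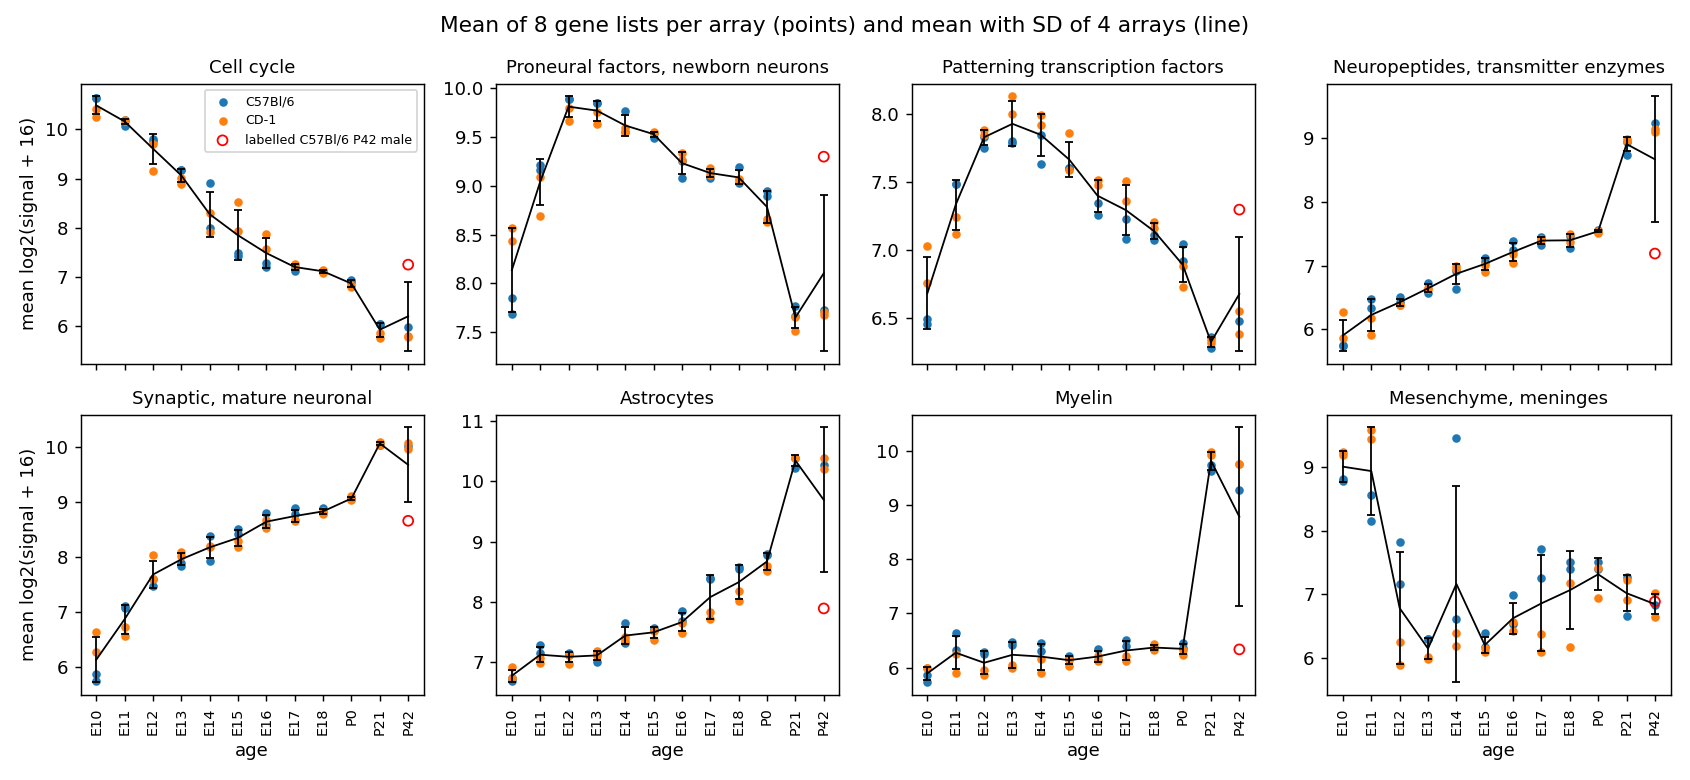
Mean log2(signal + 16) of 8 gene lists (y axes) against age (x axes), with points for single arrays coloured by strain and lines for the mean and SD of the 4 arrays of an age. Cell cycle genes are highest at E10 and patterning factors around E13 and E14, myelin genes are high at P21, and the array labelled C57Bl/6 P42 male (red ring) lies at embryonic values.

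From E14 to E18 some astrocyte, synaptic and neuropeptide genes rose, most cell cycle genes fell further, and some proneural and patterning genes fell. Ptgds, which encodes a prostaglandin D synthase of meninges and glia, rose from 114 ± 21.7 to 1900 ± 724 (3.81 ± 0.58). Apoe, the lipid carrier made by astrocytes, rose from 129 ± 17.2 to 1410 ± 438 (3.25 ± 0.46). Pla2g7, the granin Vgf, the glutamate receptor gene Grm5 and Sparcl1 rose 5.6- to 7.41-fold. Vasopressin (Avp), absent from the calls of the earlier interval, rose from 228 ± 154 to 1010 ± 340 (4.81-fold). The embryonic globins Hbb-y and Hba-x fell by 7.49 and 5.52 on the log2 scale, Hbb-y from 6700 ± 2810 to 24.8 ± 24.6. The imprinted gene Mest and the growth regulator gene Hmga2 fell by 2.18 and 1.78. Adjusted p-values of these genes were 0.000203 or lower, and all of them moved the same way in all 4 series. In all, 1916 genes were called, 1080 higher and 836 lower, and 505 changed at least 2-fold (346 up, 159 down). The count was 1194 without the array labelled C57Bl/6 E14 female, 1175 with the CD-1 arrays alone, and 2375 without the array labelled C57Bl/6 P42 male. Array weights gave 4039, and leaving out arrays or series in turn 850 to 1610.

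Cell cycle genes had 16 of 19 members lower and 0 higher (median -1.24, camera adjusted p = 7.73e-14, adjusted p = 0.0703 with an estimated correlation). Mki67, a marker of dividing cells, was at -1.76. Of 38 patterning factors 17 fell and 0 rose (26 and 2 adjusted over the list alone). Their median was -0.75 (camera adjusted p = 6.3e-10, adjusted p = 0.0412 with an estimated correlation). Gsx1, Dbx1, Sim1 and Otp fell 3.08-, 3.05-, 2.64- and 2.16-fold, while Nkx2-1 (-0.31, adjusted p = 0.478), Dlx1 (-0.61, adjusted p = 0.218) and Lhx6 (0.92, adjusted p = 0.129) were not called. Patterning signals had 6 of 18 lower (camera adjusted p = 5.8e-05, adjusted p = 0.0412 with an estimated correlation), including Gli3 at -1.36 and Shh at -1.10. Proneural genes had 7 of 17 lower and 1 higher (camera adjusted p = 0.00434, adjusted p = 0.326 with an estimated correlation), with Neurog2 at -2.35 and Nhlh2 at -1.48. Progenitor genes had 7 of 16 lower and 1 higher (camera adjusted p = 0.00026, adjusted p = 0.146 with an estimated correlation), with the filament gene Nes at -1.27. Red blood cell genes fell in 3 of 5 cases (camera adjusted p = 2.22e-06, adjusted p = 0.0412 with an estimated correlation). Imprinted genes fell in 7 of 13 cases and rose in 1 (camera adjusted p = 0.00026, adjusted p = 0.0703 with an estimated correlation), including the cell cycle inhibitor gene Cdkn1c at -1.71. Adjusted over the list alone, the numbers lower were 18, 8, 8, 8 and 4 for cell cycle, patterning signals, proneural, progenitor and red blood cell genes.

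Neuropeptide and transmitter genes had 8 of 24 members higher and 0 lower by E18 (8 and 1 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 0.000263, adjusted p = 0.311 with an estimated correlation), with gastrin-releasing peptide (Grp) at 1.69, neurotensin (Nts) at 1.51 and Npy at 1.03. Pmch (0.37, adjusted p = 0.598), Hcrt (0.04, adjusted p = 0.964) and Pomc (-1.14, adjusted p = 0.0951) were not called. Synaptic genes had 10 of 25 higher and 0 lower (camera adjusted p = 2.2e-07, adjusted p = 0.176 with an estimated correlation), with Gad1 at 1.25 and Snap25 of the vesicle fusion machinery at 1.11. Astrocyte genes had 6 of 14 higher and 1 lower (median 0.74, camera adjusted p = 0.00026, adjusted p = 0.266 with an estimated correlation), among them Apoe at 3.25 and the water channel gene Aqp4 at 1.76. Oligodendrocyte precursor genes had 2 of 7 higher (Olig1 1.53, Gpr17 1.42; camera adjusted p = 0.00974, adjusted p = 0.146 with an estimated correlation). Thalamic markers had 3 of 6 higher (camera adjusted p = 0.0316, adjusted p = 0.146 with an estimated correlation) and cholesterol synthesis genes 2 of 11 (camera adjusted p = 0.0031, adjusted p = 0.255 with an estimated correlation). Apart from the neuropeptide list, the counts of these lists were the same adjusted over the list alone. The other lists were not called by camera (adjusted p between 0.0641 and 0.973), and 0 of 11 myelin genes, 0 of 16 clock genes, 0 of 10 mesenchyme genes and 1 of 12 microglial genes were called. The array labelled C57Bl/6 E14 female raised the E14 mean of the mesenchyme list (9.46 against 6.19 to 6.61 in the other E14 arrays). Without this array camera called 2 further lists.

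Between birth and weaning age (P21) myelin, astrocyte and neuropeptide transcripts rose, and genes of immature neurons fell. Ugt8a, an enzyme of myelin lipid synthesis, rose from 36.2 ± 8.29 to 1400 ± 209, 27.2-fold. Mobp rose from 46.1 ± 12 to 1590 ± 306 and the myelin glycoprotein gene Mog from 8.11 ± 6.1 to 500 ± 124 (25.9- and 21.5-fold). Oxytocin (Oxt) rose from 534 ± 55.3 to 5260 ± 964 (3.25 ± 0.42) and orexin (Hcrt), a peptide of wakefulness, from 136 ± 30.1 to 1430 ± 427. Pmch rose from 563 ± 145 to 3860 ± 694 and Avp from 1010 ± 157 to 4420 ± 1310. Fam107a, Itih3, Aldh1a1 and the neurotensin receptor gene Ntsr2 rose 15.0- to 22.1-fold. Cxadr, an adhesion molecule and virus receptor of the developing brain, fell from 1380 ± 79.9 to 67 ± 25.9 (-4.12 ± 0.42). Sox11 fell 13.6-fold, St8sia2, which adds polysialic acid to NCAM, 10.5-fold, and Dpysl3, Dcx and Cd24a 9.43-, 9.01- and 8.01-fold. Adjusted p-values of these genes were 0.000152 or lower, with the same sign in all 4 series. In all, 4740 genes were called, 2441 higher and 2299 lower, of which 1393 changed at least 2-fold (806 up, 587 down). The fit without the array labelled C57Bl/6 P42 male gave 5020 calls. With the beta-actin ratio, which was high in both C57Bl/6 P21 arrays, as a covariate 3105 were called, and 15 of 92 named genes lost their call. The covariate fit kept the array labelled C57Bl/6 P42 male.

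Myelin genes had 10 of 11 members higher and 0 lower (median 3.69, camera adjusted p = 1.33e-13, adjusted p = 0.115 with an estimated correlation). Astrocyte genes had 12 of 14 higher (camera adjusted p = 1.69e-06, adjusted p = 0.255 with an estimated correlation), among them S100b at 3.40 and Slc1a2 at 2.98. Oligodendrocyte precursor genes had 3 of 7 higher (camera adjusted p = 0.0202, adjusted p = 0.284 with an estimated correlation), with Gpr17 at 2.43. The neuropeptide and transmitter list had 15 of 24 higher and 0 lower (median 1.64, camera adjusted p = 4.91e-07, adjusted p = 0.255 with an estimated correlation). Cartpt was at 2.85 and Pomc at 1.65, and Npy at 0.16 (adjusted p = 0.659) was not called. Synaptic genes had 16 of 25 higher and 0 lower (camera adjusted p = 2.04e-06, adjusted p = 0.29 with an estimated correlation), led by the potassium channel gene Kcna1 at 3.49 and Vamp1 at 2.82. Clock genes had 12 of 16 higher and 0 lower (13 and 0 adjusted over the list alone). Their median was 1.23 (camera adjusted p = 2.25e-06, adjusted p = 0.115 with an estimated correlation), with Dbp, a clock output gene, at 3.40, Bhlhe40 at 2.64 and Nr1d2 at 1.92. Microglial genes had 6 of 12 higher (Ctss 1.63, Csf1r 1.46; camera adjusted p = 0.0182, adjusted p = 0.3 with an estimated correlation). Blood vessel genes had 5 of 12 higher (glucose transporter gene Slc2a1 1.76; camera adjusted p = 0.0305, adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone, the other counts were the same except for 4 precursor genes higher.

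Proneural and newborn neuron genes had 11 of 17 members lower at P21 and 0 higher (camera adjusted p = 7.07e-06, adjusted p = 0.255 with an estimated correlation), with Sox4 at -2.53. Cell cycle genes had 13 of 19 lower (camera adjusted p = 1.2e-05, adjusted p = 0.29 with an estimated correlation), with Cdk1, the mitotic kinase, at -2.37. Patterning factors had 15 of 38 lower and 0 higher (camera adjusted p = 0.000766, adjusted p = 0.29 with an estimated correlation). Lhx6 fell by 1.51, Dlx1 by 1.34 and Nkx2-1 by 0.82, while Otp (-0.43, adjusted p = 0.263) was not called. Cortical markers had 4 of 6 lower (Neurod6 -2.17, Neurod2 -1.72; camera adjusted p = 0.0186, adjusted p = 0.29 with an estimated correlation). Cholesterol synthesis genes had 4 of 11 lower (Fdps -2.04, Sqle -1.35; camera adjusted p = 0.0135, adjusted p = 0.297 with an estimated correlation). Adjusted over the list alone 12, 14, 16, 4 and 4 members of these lists were lower. The other lists were not called by camera (adjusted p between 0.108 and 0.979). Progenitor genes had 3 of 16 higher and 6 lower, with Vim at -1.70 and Prom1 at 1.19. Hormone receptors had 4 of 18 higher and 1 lower (3 and 0 adjusted over the list alone), with the progesterone receptor gene Pgr at 1.68. Imprinted genes had 2 of 13 higher and 5 lower (2 and 6 adjusted over the list alone) and patterning signals 1 of 18 higher and 3 lower (1 and 2).

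**Figure D3:**
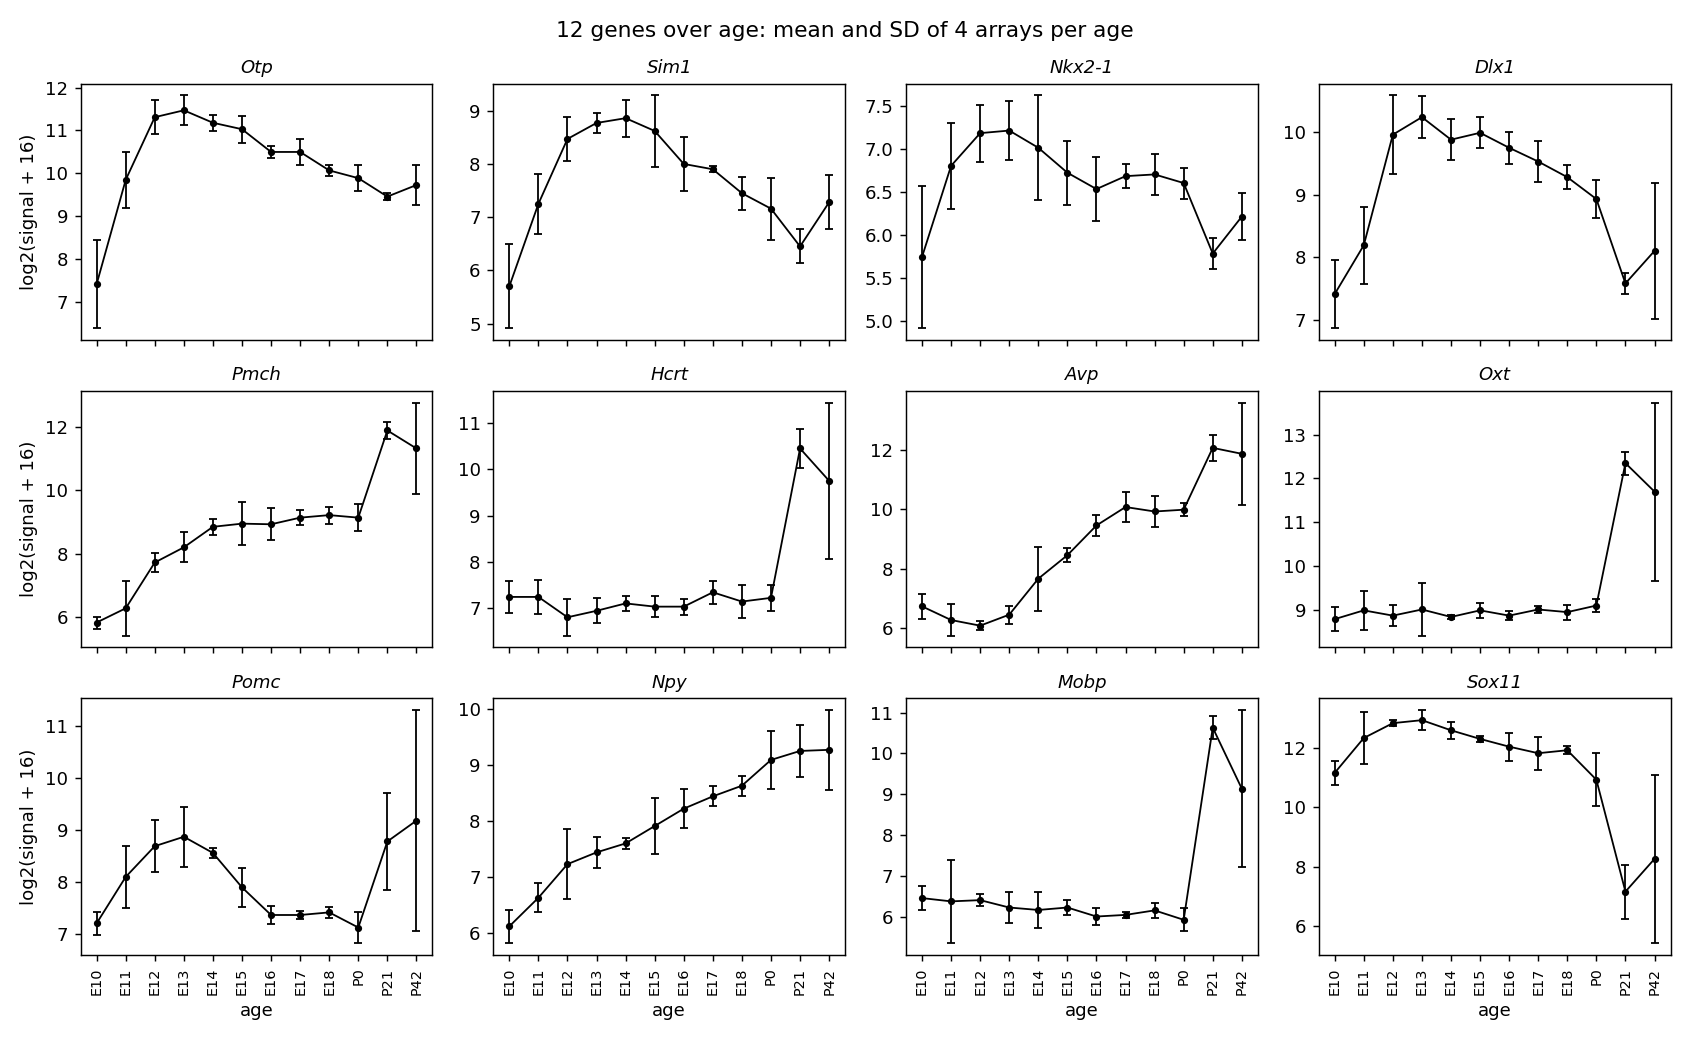
Mean and SD of log2(signal + 16) over the 4 arrays of each age (y axes) against age (x axes) for 12 genes. Otp, Sim1, Nkx2-1 and Dlx1 are highest at E13 or E14, Avp and Pmch climb from mid-gestation, and Hcrt and Oxt are flat until P0 and high at P21 and P42, where the P42 means include the array labelled C57Bl/6 P42 male.

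Key genes of hypothalamic development reached their highest mean log2 levels at different ages. Rax, Six6 and Shh, which act in early specification of the region, were highest at E11, Neurog2 at E12, Nkx2-1, Otp, Dlx1 and Six3 at E13, Sim1 at E14 and Lhx6, a gene of migrating GABAergic neurons, at E16. Mean log2 levels of Avp were 6.09 at E12, 12.07 at P21 and 12.73 in the P42 arrays other than the C57Bl/6 male, and those of Pmch 5.82 at E10, 11.90 at P21 and 12.04 in those 3 arrays. Hcrt stayed between 6.80 and 7.34 from E10 to P0 and was 10.45 at P21 and 10.57 in those arrays. Pomc, the precursor of melanocortin peptides, had a mean of 8.87 at E13, 7.13 at P0, 8.78 at P21 and 9.81 in those P42 arrays, where its signal was 4690 in the C57Bl/6 female, which also held 11000 of the pituitary transcript Gh, and 469 and 301 in the CD-1 female and male (260 and 214 at P21). Cartpt had a mean of 8.56 at E13, 6.79 at E16, 9.86 at P21 and 10.30 in those arrays.

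From each age to the next, 4106 genes changed from E10 to E11 and 3098 from E11 to E12, and the 4740 genes called between P0 and P21 made up most of the rest of the 11953 calls. Limma called 0 genes at the steps to E13, E14, E15, E16 and E18 (897, 1288, 711, 723 and 115 at an unadjusted p under 0.05). With array weights the counts at these steps were 282, 443, 6, 53 and 0, and 8 from E16 to E17 and 222 from E18 to P0, so the low counts depend on that setting. At the step to E14 an offset of 64 gave 14 genes, the beta-actin covariate 15 and leaving out the C57Bl/6 E14 female 42. The globin Hbb-y was the only gene called from E16 to E17 (-3.40 ± 0.50; 296 unadjusted). From E18 to P0 7 genes were called (918 unadjusted), the histone gene H3f3b at 1.92, Zfp322a at -0.82, Ankrd37 at -0.96, and Pnrc1, Gm3515, Mtfr1 and Trmt1l, also lower. The total without the array labelled C57Bl/6 P42 male was 13389, with 68 genes at the step to E14 and 32 from E18 to P0. Among the latter were angiotensinogen (Agt) at 2.01 and the activity-dependent factor Egr1 at 1.53. The step from E10 to E11 gave 523 genes without the C57Bl/6 females, 1195 without the C57Bl/6 males and 64 with CD-1 arrays alone, and the step from E11 to E12 1318 without the CD-1 females. The median array signal in C57Bl/6 (female and male) was 50.6 and 51.7 at E10 and 90.5 and 77.5 at E11. In CD-1 it was 48.9 and 66.3 at E10 and 67.0 and 52.3 at E11. The calls from E10 to E11 were not separated from this shift of the C57Bl/6 arrays. From E18 to P0 0 genes were called without the C57Bl/6 females, 1 without the CD-1 females, 1 without the CD-1 males, 15 with the beta-actin covariate and 134 with CD-1 arrays alone. The call of Hbb-y was lost without the C57Bl/6 females or the CD-1 females. The genes of these steps were named after their values were seen. The total was 6769 without the C57Bl/6 females, 7961 without the C57Bl/6 males and 7739 with CD-1 arrays alone.

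Between P21 and P42 the fit of all arrays called 1 gene, Spats2, which rose from 82.5 ± 80.3 to 241 ± 66.6 (1.63 ± 0.29, adjusted p = 0.0241), with 978 genes at an unadjusted p under 0.05. When the array labelled C57Bl/6 P42 male was left out its change was 1.36 (adjusted p = 0.702), and limma called 0 genes (338 unadjusted). The call of Spats2 was also lost without the C57Bl/6 P21 female, the C57Bl/6 P21 male or the CD-1 P21 male (adjusted p = 0.263, 0.114 and 0.23), while 17 genes were called without the C57Bl/6 P42 female, 3 without the CD-1 P42 female and 2 without the CD-1 P21 female. None of the neuropeptide genes that rose after birth was called: Oxt was at -0.64, Hcrt at -0.69, Pmch at -0.58 and Avp at -0.20 (adjusted p of 0.709 or more). Without the array labelled C57Bl/6 P42 male all 4 turned to the other sign, Oxt at 0.40, Hcrt at 0.17, Pmch at 0.21 and Avp at 0.63, and none was called (adjusted p = 1 each). In 29 lists 0 members were called over all genes, but camera called 12 lists in the fit of all arrays. Myelin genes were lower (7 of 11 adjusted over the list alone, camera adjusted p = 1.11e-10), and each of the 12 lists had an adjusted p of 0.124 or more with an estimated correlation. In the fit that left out the array labelled C57Bl/6 P42 male 2 lists were called, neuropeptide and transmitter genes (median 0.24, camera adjusted p = 0.000392) and pituitary genes (median 0.50, camera adjusted p = 0.00254), both higher at P42. These 2 calls used the preset correlation alone, and an estimated correlation was not tried in that fit. Growth hormone (Gh), a pituitary transcript, stood at 6390 in the C57Bl/6 P21 female and 11000 in the P42 female, against 5.77 to 35.6 in the CD-1 P21 and P42 arrays, and Pomc at 4690 in the C57Bl/6 P42 female. Ttr of the choroid plexus stood at 5000 in the C57Bl/6 P21 female and 5130 in the CD-1 P21 male, against 87.2 and 119 in the other P21 arrays.

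CD-1 and C57Bl/6 tissue differed in the level of many genes by small amounts and of few by large ones. Rpgrip1, a gene of the photoreceptor cilium, was at 215 ± 94.1 in CD-1 and 2880 ± 1440 in C57Bl/6 (n = 24 arrays each; -3.60 ± 0.09) and lower in CD-1 in 24 of 24 matched pairs. The noncoding RNA gene Rmst was at -2.92, Mir1931 at -2.34, Fgf14 at -1.86, Snhg11 at -1.77, the motor protein gene Myo7a at -1.73 and H2-T24 of the histocompatibility complex at -1.71. Each was lower in CD-1 in at least 23 of 24 pairs. Tmem87a was at 342 ± 73.3 in CD-1 against 55.6 ± 61.8 (2.64 ± 0.16), higher in 24 of 24 pairs. Among the genes that followed were Zscan29 (1.94), Gas7 (1.91), the heme-binding protein gene Hebp1 (1.80) and Cap1 and Hddc3 (3.3- and 3.26-fold). Lhx8, a factor of cholinergic and preoptic neurons, was at 529 ± 283 against 180 ± 140 (1.52 ± 0.23, higher in 21 of 24 pairs), and Lhx6 and Sst were higher by 0.95 and 0.83. Adjusted p-values of these genes were 1.11e-05 or lower. Limma called 6669 genes, 3438 higher and 3231 lower in CD-1, and 86 by 2-fold or more (35 and 51). The count was 7085 without the array labelled C57Bl/6 P42 male. In females alone 4347 were called, in males alone 2831, at P21 and P42 alone 1231 (4773 when the array labelled C57Bl/6 P42 male was left out of these) and with the beta-actin ratio as a covariate 4305, of which 3834 were shared with the 6669. With that covariate 27 of 101 named genes lost their call. The covariate fit kept the array labelled C57Bl/6 P42 male. In the fit that gave 4773 the C57Bl/6 arrays are those with the high beta-actin ratios, so strain goes with RNA quality there. Leaving out all C57Bl/6 females gave 3967 and leaving out all CD-1 females 3594.

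Some strain differences were smaller at the later ages or rested on a single probe set. At P21 and P42 alone Lhx8 differed by 0.11 (adjusted p = 0.891) and Lhx6 by -0.03, and with the array labelled C57Bl/6 P42 male left out by 0.69 (adjusted p = 0.00661) and 0.38 (adjusted p = 0.111). Of 101 named genes 57 lost their call at these ages, with fewer arrays, and 9 changed sign. With that array left out 30 lost their call, 8 changed sign and 58 kept their side of the threshold. Among those lost were C1qa at 0.1 (adjusted p = 0.68), Trem2 at -0.19 (adjusted p = 0.682) and Flt1 at -0.32 (adjusted p = 0.149). The other probe sets of Cap1, Rmst, Snhg11 and Gm6958 were called in the same direction and those of Hddc3 and Gas7 were not. Fgf14 had 1 called the same way and 1 the opposite way. No list was called by camera between the strains. Genes known to vary between inbred strains had 5 of 11 members higher in CD-1 and 0 lower (camera adjusted p = 0.0871), H2-D1 by 1.34, the glyoxalase gene Glo1 by 1.23 and the heme synthesis gene Alad by 0.95. Blood vessel genes had 1 of 12 higher and 7 lower (median -0.37, camera adjusted p = 0.0871), with the receptor gene Flt1 at -0.63 and Rgs5 at -0.62. Patterning factors had 8 of 38 higher and 8 lower (7 and 8 adjusted over the list alone), with Six3 at -0.39 and Six6 at -0.47. Hormone receptors had 2 of 18 higher and 7 lower, synaptic genes 7 of 25 higher and 4 lower, and cholesterol synthesis genes 6 of 11 higher and 4 lower, with Fdps at 0.96 and Fdft1 at 0.44. Neuropeptide genes had 5 of 24 higher and 1 lower (3 and 1 adjusted over the list alone) and microglial genes 5 of 12 higher and 3 lower, with C1qa at 0.92 and Trem2 at -0.68. At P21 and P42 with the array labelled C57Bl/6 P42 male left out, Pomc (-2.3), Hcrt (-0.82), Pmch (-0.43) and Oxt (-0.4) were called lower in CD-1. There Npy (0.65), Sst (0.59) and Avp (0.52) were called higher (adjusted p of 0.0131 or lower for all of these). The Pomc value includes the C57Bl/6 P42 female with its high pituitary transcript Gh. The C57Bl/6 arrays of this fit have beta-actin 3' to 5' ratios of 3.77 to 4.49, against 1.10 to 1.21 in its CD-1 arrays. Strain can therefore not be told apart from RNA quality in these late calls. Cell cycle genes had 2 of 19 higher and 4 lower (1 and 1 adjusted over the list alone), with Mki67 at -0.74, and proneural genes 0 higher and 4 of 17 lower (0 and 2). Of 11 myelin genes 0 were called. Progenitor genes had 4 of 16 higher and 3 lower, patterning signals 4 and 4 of 18 (3 and 4 adjusted over the list alone), astrocyte genes 3 and 2 of 14, imprinted genes 3 and 2 of 13, clock genes 2 and 4 of 16 (2 and 3) and immediate early genes 3 and 2 of 10. In the lists of oligodendrocyte precursors, red blood cells, choroid plexus, ependymal cells, pituitary, mesenchyme, cortex, striatum and thalamus 0 to 2 members were called each way (camera adjusted p from 0.0871 to 0.999 over all lists). Adjusted over the list alone, pituitary genes had 3 of 5 lower, mesenchyme genes 1 of 10 lower and cortical markers 1 of 6 higher.

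In 1401 genes the strain difference was not the same at E10 to P0 as at P21 and P42 (765 with a higher CD-1 value relative to C57Bl/6 at the later stage, 636 with a lower one, 255 by 2-fold or more). With median centring the lower calls outnumbered the higher ones. The sodium channel subunit gene Scn2b differed by 0.29 between the strains at E10 to P0 and by 2.69 at P21 and P42 (change 2.40 ± 0.25, adjusted p = 1.26e-07). The claudin gene Cldn10 differed by -0.19 and 2.08, the enzyme gene Got1 by 0.40 and 1.78, Card10 by -0.18 and 1.32, and Mtf2 by -0.04 and -1.07. With the array labelled C57Bl/6 P42 male left out the later differences were 2.40, 1.80, 1.61, 1.21 and -1.05, and 1548 genes were called. The 3 other late C57Bl/6 arrays are those with the high beta-actin 3' to 5' ratios. With the ratio as a covariate 2665 genes were called, 975 of them among the 1401. That fit kept the array labelled C57Bl/6 P42 male, at a ratio of 1.28 against 4.49 in the C57Bl/6 P42 female. There the covariate also follows the late embryonic profile of that array, so this count cannot separate RNA quality from it. The covariate was not tried without that array. Leaving out P21 gave 849 genes, leaving out P42 419, leaving out the C57Bl/6 males 656, the CD-1 females 244 and the CD-1 males 441.

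**Figure D4:**
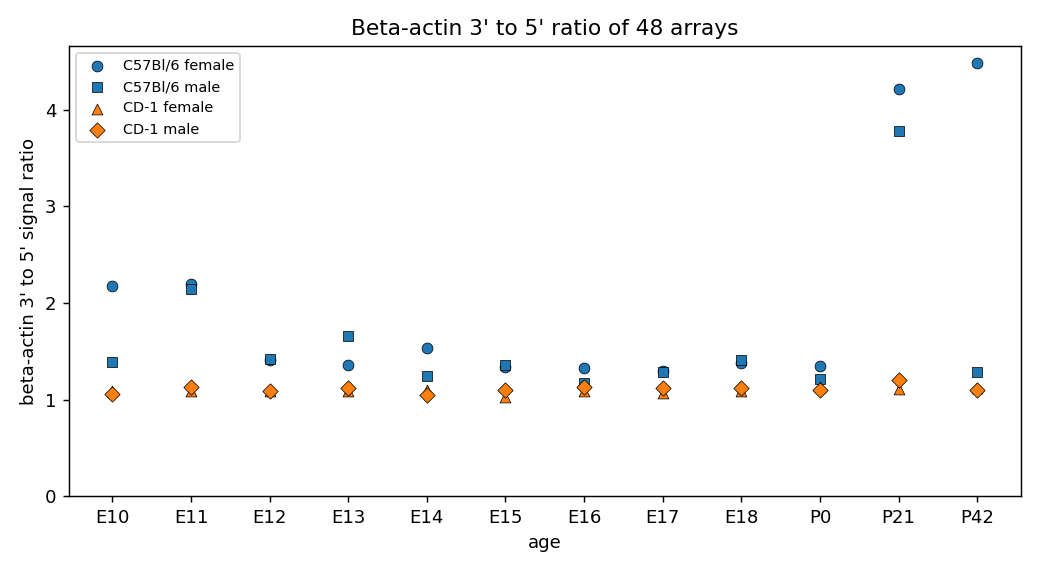
Beta-actin 3' to 5' signal ratio (y axis) of the 48 arrays by age (x axis), coloured by strain with a symbol for each sex. The 24 CD-1 arrays lie between 1.03 and 1.21, and the C57Bl/6 P21 female, P21 male and P42 female between 3.77 and 4.49.

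Males and females differed in 6 genes, all of them sex-linked. The Y-linked genes Eif2s3y, Kdm5d and Uty were higher in males by 2.47 ± 0.11, 2.25 ± 0.10 and 1.83 ± 0.11 on the log2 scale, each in 24 of 24 matched pairs. Eif2s3y stood at 122 ± 41.3 in males against 9.56 ± 11.6 in females (n = 24 each). Xist, the RNA that coats the inactive X chromosome, was lower in males (218 ± 418 against 2640 ± 631; -4.23 ± 0.21). The arrays labelled C57Bl/6 P42 male and E16 male raise its male mean and SD (male median 90.9, at most 170 in the other males), and without both arrays it was at -4.53 ± 0.10. Kdm6a and Eif2s3x, X-linked genes known to escape inactivation, were at -0.57 and -0.39, lower in males in 23 and 22 of 24 pairs. Adjusted p-values were 0.000385 or lower, and 445 genes had an unadjusted p under 0.05. In C57Bl/6 alone Kdm6a and Eif2s3x were not called (adjusted p = 0.0553 and 0.804), nor was Kdm6a without the C57Bl/6 males (adjusted p = 0.766), the CD-1 females (0.257) or the CD-1 males (0.33). Eif2s3x was not called without the CD-1 females (adjusted p = 1) or the CD-1 males (adjusted p = 0.823). In these fits of fewer arrays Kdm6a stayed at -0.55 to -0.60 and Eif2s3x at -0.31. All 3 tested Y-linked genes were higher (camera adjusted p = 4.17e-70, adjusted p = 5.8e-14 with an estimated correlation). Of 6 escape genes 2 were lower (4 adjusted over the list alone; camera adjusted p = 6.66e-17, adjusted p = 3.35e-07 with an estimated correlation), and of the X inactivation RNAs the 1 tested, Xist, was lower. In the other lists 0 members were called, and the 8 other lists called by camera were not called with an estimated correlation (adjusted p = 0.606 or more). Leaving out the array labelled C57Bl/6 P42 male gave 8 genes, with 5530601H04Rik at -0.40 and Pbdc1 at -0.30 added, and leaving out the array labelled C57Bl/6 E16 male as well gave the same 8.

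**Figure D5:**
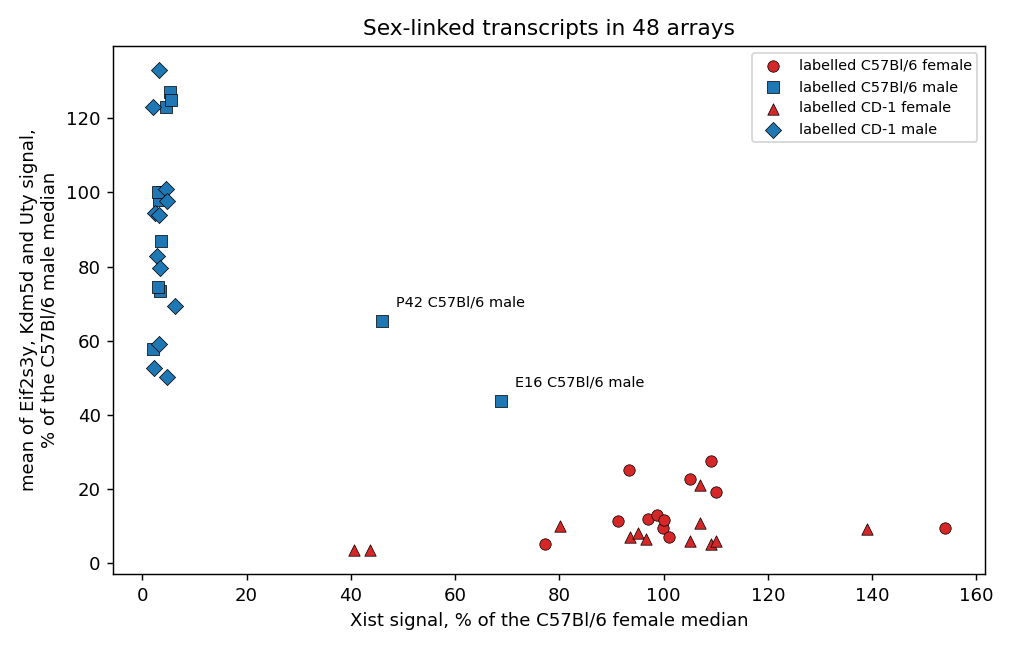
Xist signal as a percent of the median of C57Bl/6 females (x axis) against the mean of the Y-linked Eif2s3y, Kdm5d and Uty as a percent of the median of C57Bl/6 males (y axis), 1 point per array, coloured by labelled sex. Males lie at the left and females at the bottom, and the arrays labelled C57Bl/6 P42 male (45.9% and 65.3%) and C57Bl/6 E16 male (68.8% and 43.8%) lie between them.

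At E10 to P0 alone the same 6 genes were called between the sexes. At P21 and P42, 5 genes were called (1082 unadjusted): Eif2s3y at 2.39, Kdm5d at 1.64, Uty at 1.86, Xist at -3.43 and the immune checkpoint gene Cd276 at 1.25. With the array labelled C57Bl/6 P42 male left out Cd276 was not called (unadjusted p = 0.000461), Xist stood at -4.31 and 6 genes were called, among them the X-linked Ddx3x at -0.62 and Rbmx2 at -0.94, which were named after their values were seen. Gh stood at -3.90 (adjusted p = 0.0543), with its high signals in the 2 C57Bl/6 females alone (6390 and 11000), 132 in the C57Bl/6 P21 male, 23.4 in the array labelled C57Bl/6 P42 male and at most 35.6 in CD-1 arrays of either sex at these ages. Leaving out P21 gave 340 genes, leaving out P42 2, leaving out the CD-1 females 12 and the CD-1 males 598. The fits without P21, the CD-1 females or the CD-1 males kept the array labelled C57Bl/6 P42 male. Its late embryonic profile enters their counts as a sex difference. With pairs matched by age and strain as a block, 14 genes were called at P21 and P42, Gh (adjusted p = 0.00124), Kdm6a (-0.73) and the activin-binding protein gene Fst (0.60) among them. The sex difference changed with stage in 0 genes by limma (817 unadjusted), in 3 with these pairs as a block (Cd276, Gh and Fst), and in 118 without P21, 2 without the C57Bl/6 females, 1 without the CD-1 females and 288 without the CD-1 males. The strain difference changed with sex in 0 genes (391 unadjusted), and in 0 under every alternative run. The estrogen receptor gene Esr1 differed by 0.13 between males and females (adjusted p = 1), and the key genes Avp, Oxt, Pomc and Npy by -0.04, -0.22, -0.23 and -0.11 (adjusted p = 1 each).

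Placed on the age axis of the other strain, embryos of CD-1 and C57Bl/6 did not differ in stage in a uniform way. The mean difference over E11 to E18 was 0.036 days (SD 0.9, n = 8 ages, CD-1 ahead at 4 of 8, exact sign-flip p = 0.906), with CD-1 ahead by 0.80, 1.37 and 0.85 days at E12, E13 and E14 and C57Bl/6 ahead at E15, E16 and E17 (-0.85, -0.52 and -1.13 days). At E12 the CD-1 male was placed 2.43 days past its label and the CD-1 female 0.02. At E14 the array labelled C57Bl/6 E14 female was placed at -2.3 days and the C57Bl/6 male at 0.31. The simulated arrays held no strain difference in any gene, so the values of single ages cannot be read as differences in stage. Males were placed ahead of females by 0.154 days (SD 0.13, ahead at 7 of 8 ages, exact sign-flip p = 0.0312), where simulated shifts of 0 and 0.25 days were recovered as 0.061 and 0.389 days. This call was lost without E12, E15, E16, E17 or E18, with 0.162, 0.162, 0.13, 0.125 and 0.149 days and exact p from 0.0625 to 0.0781, and with 1 minus Pearson correlation as the distance (0.139 days, exact p = 0.0625) or quantile normalization (0.142 days, exact p = 0.0625).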

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

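In this part the tests of an exchange between arrays, of degraded RNA, of RNA of both sexes, of an array batch, of mesenchymal tissue and of a younger embryo (both tests), and all counts of other splits, were chosen only after the result was seen, as were the fits without single doubted arrays and with the beta-actin ratio. A sample was set apart where its gap to the nearest of the 4 arrays of its age took up more of their range than Dixon's 95% critical value for 4, which chance does in about 1 in 20 groups. Of 408 groups 28 met this, against 20.4 expected by chance, and 12 of the 28 lay in the array labelled C57Bl/6 P42 male.

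The array labelled C57Bl/6 P42 male stood apart from the other 3 P42 arrays in 10 gene lists and 2 principal components. Mean log2 levels were lower for myelin genes (6.34 against 9.29 to 9.77), astrocytes (7.89 against 10.21 to 10.4), neuropeptides (7.19 against 9.1 to 9.25), synaptic genes (8.66 against 9.96 to 10.07), the clock (6.66 against 7.92 to 8.07), microglia (6.71 against 7.76 to 7.89) and striatal markers (6.35 against 7.18 to 7.28). They were higher for proneural genes (9.3 against 7.68 to 7.73), cell cycle genes (7.25 against 5.77 to 5.98) and imprinted genes (10.03 against 9.42 to 9.45). Its PC1 score was 23.9 (others 60.69 to 65.92) and its PC2 score 21.4 (others -59.26 to -51.15).

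On a line from the mean of late embryonic C57Bl/6 arrays (0%) to that of the P21 and P42 arrays (100%), the array labelled C57Bl/6 P42 male lay at -6.7%, inside the range of single C57Bl/6 E15 to P0 arrays (-13.2 to 10.8), and late embryonic RNA under a wrong label may account for its profile. An exchange with another array of the series is argued against by the 0 of 40 arrays labelled E10 to P0 above 50% (range -22.3 to 25.8), and degraded RNA by its beta-actin ratio of 1.282 (C57Bl/6 E15 to P0 arrays 1.174 to 1.413). Its Xist level was 45.9% of the female median and its Y-linked level 65.3% of the male median, a sum of 111%, and in the array labelled C57Bl/6 E16 male the values were 68.8%, 43.8% and 113%. RNA of both sexes in these 2 samples cannot be told apart from other sources by the test used, since 4 other arrays, all labelled female, also met its bounds. The 4 did so because the lower bound lay inside the Y-linked signal of arrays labelled female, which reached 27.7%. In the other arrays labelled male Xist was at most 6.32%, so only these 2 arrays exceeded both levels. No biological explanation was tested.

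The array labelled C57Bl/6 E14 female stood apart in genes of mesenchyme and meninges (9.46 against 6.19 to 6.61), patterning signals (8.14 against 7.53 to 7.61) and PC2 (7.46 against 26.3 to 27.24). All 10 tested mesenchyme genes were higher than in the other E14 arrays, with a median log2 difference of 3.34 (0.75 to 4.81), but this list is what set the array apart, so mesenchymal tissue in the sample cannot be told apart from other sources by it. A younger embryo as the whole source of the mesenchyme genes is argued against, since the list mean of 9.46 lay above every E12 and E13 array (5.9 to 7.82) while the cell cycle mean of 8.91 lay below every E10 and E11 array (10.08 or more). Whether the embryo was also younger than its label stays open: the embryonic globin Hbb-bh1 was at 56.3 (other E14 arrays 43 to 114, E13 at least 147), but the cell cycle mean lay in the E13 range (8.89 to 9.18), above the other E14 arrays (7.91 to 8.29). No biological explanation was tested.

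The difference between the strains was many small changes, and 3 technical explanations that were tested stay open. Others, a difference in dissection among them, were not tested. The strain change at E10 to P0 correlated at -0.04 over genes with the change predicted from the beta-actin ratio, below the bound of 0.1 written for exclusion, but that bound was wrong because 54.4% of the within-age variation of the ratio came from the E10 pair, so lower RNA quality cannot be told apart here. Of 69 other probe sets of the 36 genes called at 2-fold or more, 75.4% changed the same way (91.1% between P0 and P21), between the bounds of 70% and 90% that were set for sequence variants under single probe sets. Of 5693 other probe sets of 3278 called genes, 20.6% were called the opposite way and 38% the same way (2.24% and 34.8% between P0 and P21 for changes under 2-fold), and an array batch that followed strain could not be told apart from strain, because the labels give no batch. The signal of the array control CreX also differed by strain, at 1920.3 to 4445.0 in CD-1 and 3709.2 to 18519.9 in C57Bl/6. Genetic differences between the strains stay among the open explanations.

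In 1401 genes the strain difference at P21 and P42 was not the same as at E10 to P0 by the test of the interaction, among them Scn2b (2.40), Cldn10 (2.26), Card10 (1.5), Got1 (1.38) and Mtf2 (-1.03). Of the 66 choices of 2 ages as the later stage 4, the real one among them, gave as many genes, the highest other being E11 and E13 with 1882. These choices kept the true strain labels and may hold real differences between ages. They therefore cannot decide on chance, which was not excluded.

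Other arrays stood apart in single quantities, and these may be chance, which was expected to set apart 20.4 of the 408 groups. Proneural genes were at 9.77 in the C57Bl/6 E14 male (others 9.56 to 9.59), patterning factors at 7.86 in the CD-1 E15 male (7.59 to 7.6) and hormone receptors at 7.11 in the C57Bl/6 P21 male (7.16 to 7.17). Astrocyte genes were at 6.96 in the CD-1 E12 female (7.11 to 7.14) and 10.22 in the C57Bl/6 P21 female (10.39 to 10.4), and imprinted genes at 9.99 in the C57Bl/6 E16 female (10.15 to 10.17). In the CD-1 E11 male microglial genes were at 7.03 (6.83 to 6.86) and ependymal genes at 5.7 (6.07 to 6.13). The median signal was 66.3 in the CD-1 E10 male (48.9 to 51.7) and 51.7 in the CD-1 P42 female (60.3 to 61.6). The Gapdh 3' to 5' ratio was 0.759 in the CD-1 E13 female (0.82 to 0.83) and 2.1 in the C57Bl/6 P42 female (0.78 to 0.84), where the beta-actin ratio was 4.49 (1.1 to 1.28).

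Other splits of the arrays tested whether chance can be excluded. It was excluded for E14 against E10 (1 of 35 splits gave as many genes, 7353 against 5069 in the highest other, which grouped the C57Bl/6 E14 female with 3 E10 arrays), E18 against E14 (1 of 35, 1916 against 1) and P21 against P0 (1 of 35, 4740 genes, the highest other reaching 10.9% of that). With 100 redraws it was excluded for differences across the ages (1 of 100, 11008 against 2), steps between neighbouring ages (1 of 100, 11953 against 4064), strain (1 of 100, 6669 against 3594) and sex (1 of 100, 6 against 0). For sex at P21 and P42 the redraws could not decide (1 of 100, 5 against 2). That effect rests on the pairs of P21 and P42 alone, so a redraw could keep its real grouping. Pairs of earlier ages were redrawn too, and they enter the spread. Chance was not excluded for P42 against P21, where 10 of 35 splits gave as many (1 against 1371 in the split that separates the strains, a structure of the samples). The change of the sex difference with stage called 0 genes by limma (817 unadjusted), as few as any of the 66 choices (66 of 66, highest 2 for E11 and P42), and that of the strain difference with sex 0 (391 unadjusted; 100 of 100, highest 2).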

How the results depend on the processing

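In this part the fits without doubted arrays, with CD-1 arrays alone, with matched pairs as a block and with the beta-actin ratio as a covariate were chosen only after the data were seen. Counts other than those of single steps between ages stayed within 1.5 times and named genes and lists that were called kept their direction except as follows, and the cause was not tested unless stated. Between P21 and P42 (1 gene) an offset of 4 gave 2, an offset of 64 gave 3 and eBayes without trend 3. The limma count was 0 with every probe set, array weights, the 8 arrays compared, the array labelled C57Bl/6 P42 male left out (338 at an unadjusted p under 0.05) and the beta-actin covariate. With every probe set, a larger number of tests, the counts were 22521 across ages, 14157 for E14 against E10, 2919 for E18 against E14, 8773 for P21 against P0, 16479 for strain (40% higher against 51.6%), 22 for sex, 18 for sex at P21 and P42, 2505 for strain by stage and 21622 for neighbouring ages. Sex at P21 and P42 (5) gave 3 under the stricter filter and 8 with array weights. Array weights gave 4039 for E18 against E14 and 3354 for strain by stage. E18 against E14 gave 3263 with the 8 arrays compared and 1175 with CD-1 arrays, which gave 7739 for neighbouring ages. Strain gave 4347 in females and 2831 in males, with fewer arrays in each, and 1231 at P21 and P42 (4773 there without the array labelled C57Bl/6 P42 male). The C57Bl/6 arrays behind the 4773 are those with the high beta-actin ratios. With the beta-actin covariate, in fits that kept the array labelled C57Bl/6 P42 male, P21 against P0 gave 3105, strain 4305 and strain by stage 2665. Higher calls were 64.3% of strain calls under the stricter filter, 61.2% with quantile normalization, and 40.6% of strain by stage calls with median centring (54.6% in the main fit). Camera made 54 calls of lists, of which 5 were left with an estimated correlation. It made 37 without the array labelled C57Bl/6 P42 male (35 shared), and fry, which tests each list against no change, made 61 (34 shared). Males were ahead of females by 0.139 days with 1 minus Pearson correlation and 0.142 with quantile normalization, no longer called.

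Leaving out arrays, ages or series in turn gave 9629 to 11314 genes across ages, 6246 to 7764 for E14 against E10, 850 to 1610 for E18 against E14, 3699 to 4528 for P21 against P0, 0 to 17 for P42 against P21, 3594 to 7186 for strain, 4 to 8 for sex, 2 to 598 for sex at P21 and P42, 0 to 288 for sex by stage, 244 to 1781 for strain by stage, 0 to 0 for strain by sex, 6769 to 12160 for neighbouring ages, 0.125 to 0.203 days for males against females and -0.232 to 0.251 days for CD-1 against C57Bl/6. The counts of 598 and 288 came from fits that kept the array labelled C57Bl/6 P42 male. Directions reversed for the strain change of Ddx3x (0.12) and Dlk1 (-0.05) with probe sets that can match several transcripts used last, and at P21 and P42 alone for Lhx6 (-0.03), Mc3r (0.18), Esr1 (0.2), Alas2 (0.12), Foxj1 (0.27), Dcn (0.29), Col3a1 (0.12), Mest (-0.25) and Rax (0.03). With the array labelled C57Bl/6 P42 male left out of these ages they reversed for Mc3r (0.26), Alas2 (0.65), Foxj1 (0.41), Dcn (0.04), Col3a1 (0.47), Dlg4 (-0.11), Aldoc (-0.02) and Nkx2-1 (0.1), while Lhx6 was at 0.38 with its sign kept. They also reversed for the strain change of Gh with the beta-actin covariate (0.88), for Otx2 (0.15) and Tshb (-0.27) from E10 to E14 in CD-1 arrays, and without the array labelled C57Bl/6 P42 male for the cell cycle list (camera adjusted p = 0.312) and the neuropeptide list (0.000392) between P21 and P42 and the neuropeptide list between the sexes (0.922). The 4 series of strain and sex as a block gave 6657 strain calls, and 100 of 101 named genes kept their call. The labels give no replicate numbers. The array labelled C57Bl/6 P42 male was kept in the matched fits that follow. With arrays matched by age and strain or by age and sex as a block, sex at P21 and P42 gave 14 genes, sex by stage 3, sex 7, strain 6260 (6221 shared), strain by stage 1068 (1052 shared) and strain by sex 0 (795 unadjusted), and 94 of 101 named strain genes kept their side of the threshold.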

Other observations

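In this part the test of a stage difference between the strains was written before its result was seen, and the genes below were chosen only after the result was seen.

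Peptide, enzyme and imprinted genes outside the key set followed separate courses. Tac2, a peptide gene of arcuate neurons, had mean log2 levels of 5.83 at P0, 8.57 at P21 and 9.07 in the P42 arrays other than the C57Bl/6 male, and Th of dopamine synthesis 6.65, 8.50 and 8.47. Gal was at 5.74 at E12, 9.43 at P21 and 9.78 in those 3 P42 arrays. Crh, the stress peptide gene, was at 7.30 at E16, 6.11 at P0 and 8.22 at P21. The imprinted growth factor gene Igf2 was at 11.58 at E10, 8.19 at E13 and 9.85 at P0, and Meg3 was highest at E13 (12.55) and lower in CD-1 than in C57Bl/6 (-0.73, with 8 of 10 other probe sets called the same way). Each of these 6 genes differed across the ages by the limma F test (adjusted p of 1.79e-07 or lower).

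Among genes whose strain difference changed with stage, the acute phase gene Serpina3n differed by -0.17 at E10 to P0 and 2.74 at P21 and P42, Lcat of cholesterol transport by -0.38 and 1.27, and Pttg1, securin of mitosis, by 0.45 and -2.50. Without the array labelled C57Bl/6 P42 male the later differences were 2.15, 1.14 and -2.97.

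A uniform difference in stage between the strains is argued against as the source of their expression difference, since the strain change correlated at 0.03 over genes with the change from E10 to E18. Xist in the CD-1 females of P21 and P42 stood at 40.6% and 43.6% of the C57Bl/6 female median. In the C57Bl/6 E14 female Col1a1 stood at 1640 against 73.2 in the other E14 arrays, Dcn at 536 against 18.1 and Lum at 598 against 42.7.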
